A study of Arabidopsis thaliana with 4 samples.

How the data were processed

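Transcript levels were measured in whole Arabidopsis thaliana seedlings of the wild type Col-0 and of the double mutant voz1 voz2, with 2 samples of each. Per the labels' protocols, seedlings were kept for 3 days at 4 °C in darkness and then grown on agar medium at 22 °C under 16 h of light and 8 h of darkness until 14 days of age, at a light intensity of about 130 μmol per square metre per second. Total RNA was amplified and labelled with Cy3 from 500 ng per sample, and each sample was hybridised to its own array. The labels do not say whether the 2 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

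The scanner intensity values were made with Agilent Feature Extraction 11.5.1.1, per the file headers, on a linear scale, with a spatially detrended background subtracted and low spots replaced by a substitute value. The mean spot intensity and the median local background intensity before any correction are also given per the file headers. The authors' deposited value table holds log2 values. For about 99% of probes on each array (98.9% to 99.1%) they equal the log2 scanner signal minus a constant within 0.01, and that constant lies close to the array's 75th percentile. The medians of its columns were -2.68 and -2.56 for Col-0 and -2.76 and -2.63 for voz1 voz2. Genes are not centred in it, and it holds levels of single arrays, so no direction of a ratio is involved; how replicate spots were merged in it is not given in the sources used here. All 4 arrays lay on 1 slide and were scanned on 1 day, so neither slide nor scan day separates the groups.

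The main values were log2 processed intensities minus each array's 75th percentile, after control spots and spots marked as outliers had been left out and spots of a probe averaged. The arrays carried 43613 probes of 60 bases. Probes were named through the RefSeq table of assembly TAIR10.1, used for names and for the order of genes only: 35858 probes had 1 gene, 463 had several and 7292 had none, and 26200 genes had at least 1 probe. Each gene was represented by its brightest probe over the 4 arrays, and a gene was tested if that probe was well above background on both arrays of at least 1 group, which left 21385 genes. Between 76.7% and 80.2% of spots per array were well above background, and 0 spots were saturated. The precision of every comparison is limited by the number of arrays.

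Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. "Rose" and "fell" are used for genes past that threshold, in voz1 voz2 relative to Col-0. Log2 fold changes are given with limma's standard error (SE), and levels as mean ± SD with n = 2 arrays. A probe not well above background on any array of a group has only a bound there: the mean of the brighter group was set against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal, and the result is given as "at least N-fold".

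Before the data were examined, 20 gene lists, 24 keywords for families in the array's gene descriptions, the test of genes near VOZ1 and VOZ2, the alternatives, and the rule for named genes were fixed. That rule names VOZ1, VOZ2, FT, TSF, SOC1, FLC, CO, GI, AP1, LFY, FUL, MAF2 to MAF5, SVP and PR1, the 10 largest rises and 10 largest falls among genes past the threshold with both mutant arrays beyond both Col-0 arrays, and for each list the 2 members with the smallest p that rose and the 2 that fell. Other genes named as examples were chosen after their values were seen. The 18 lists with at least 3 measured genes and the 21 families with at least 10 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists or over families. With an estimated correlation 0 of the 18 lists passed (smallest adjusted p = 0.445), and fry, which asks whether a list's genes move on balance 1 way, also passed 0 lists (smallest adjusted p = 0.0624).

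The code was tested on simulated data for the comparison of voz1 voz2 with Col-0, over 21385 genes and 20 runs. With 200 genes changed, 0.97% of changes of 1 on the log2 scale, 68.9% of changes of 2 and 91.7% of changes of 3 were recovered; with 2500 genes changed the shares were 61.6%, 95.6% and 98.8%. A mean of 4.79% and 4.47% of the calls were false in these settings. For camera, a list shifted by -1 passed in 20 of 20 runs at the preset correlation and in 0 of 20 with an estimated correlation. The simulated genes varied independently of each other, unlike most lists that passed camera in the real data. There the estimated correlation was 0.92 for touch and wounding, 0.85 for heat shock, 0.58 for photosynthesis and 0.52 for jasmonate and ethylene defence. It was 0.44 for senescence, 0.12 for salicylic acid defence, 0.08 for flavonoid synthesis and -0.08 for phosphate starvation. The simulated camera results do not cover lists as correlated as the highest of these. The spread of the simulated genes was drawn from the prior that limma fitted, with no effect of array, batch or culture. The share of false calls therefore checks the code and does not estimate false calls in the real data.

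Alternatives changed 1 choice at a time: normexp background correction with an offset of 50, quantile normalization, scaling to each array's median, the authors' deposited values, no filter on dim probes, a filter for signal above background on all 4 arrays, the mean of a gene's probes, an intensity trend in eBayes, no moderation of the variances, a replicate block, leaving out each array, counting probes, a fold threshold of 2, and the other set tests. Python 3.11.15 with pandas 2.3.3 read the files and Matplotlib 3.10.9 drew the plots. No coordinates are given, because the gene table's assembly was not matched to the array design's own build.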

Results

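Gene expression was measured with 1-colour arrays in whole seedlings of Col-0 and of voz1 voz2, which carries mutations in VOZ1 and VOZ2, a pair of related zinc finger transcription factors. Plants were 14 days old and grown in long days, and each group had 2 samples. Across genes, the correlation of log2 levels was 0.986 between the Col-0 arrays and 0.989 between the voz1 voz2 arrays, against 0.941 to 0.957 between groups. The median absolute log2 difference between replicates was 0.241 in Col-0 and 0.189 in voz1 voz2. The title of the series places the comparison in the study of flowering in response to day length, and the question it addresses is which transcripts differ when both VOZ genes are disrupted.

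The disrupted genes were examined first. VOZ2 (AT2G42400) fell by 6.32 on the log2 scale (SE 0.206, limma adjusted p = 0.00171), a fold of 79.9, from 0.73 ± 0.32 in Col-0 to -5.59 ± 0.01 in voz1 voz2 (SD, n = 2). VOZ1 (AT1G28520) fell by 1.56 on its brightest probe (SE 0.30, adjusted p = 0.0347), a fold of 2.94. The other VOZ1 probes differed in direction: tested among 29439 probes, the second brightest fell by 2.08 (adjusted p = 0.0293) and the dimmest rose by 2.34 (adjusted p = 0.0204), while the brightest probe had an adjusted p of 0.0689 there. Where these probes lie relative to the disrupted part of either gene was not determined here, and a probe outside that part does not check the genotype. The VOZ1 call was lost without Col-0 replicate 1 (log2 fold change -1.39, adjusted p = 0.0925) and without voz1 voz2 replicate 2 (-1.18, 0.0816), and with the mean of its probes the log2 fold change was -0.43 (adjusted p = 0.253); over 13 alternatives without a replicate block the adjusted p ranged from 0.0142 to 0.281.

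**Figure D1:**
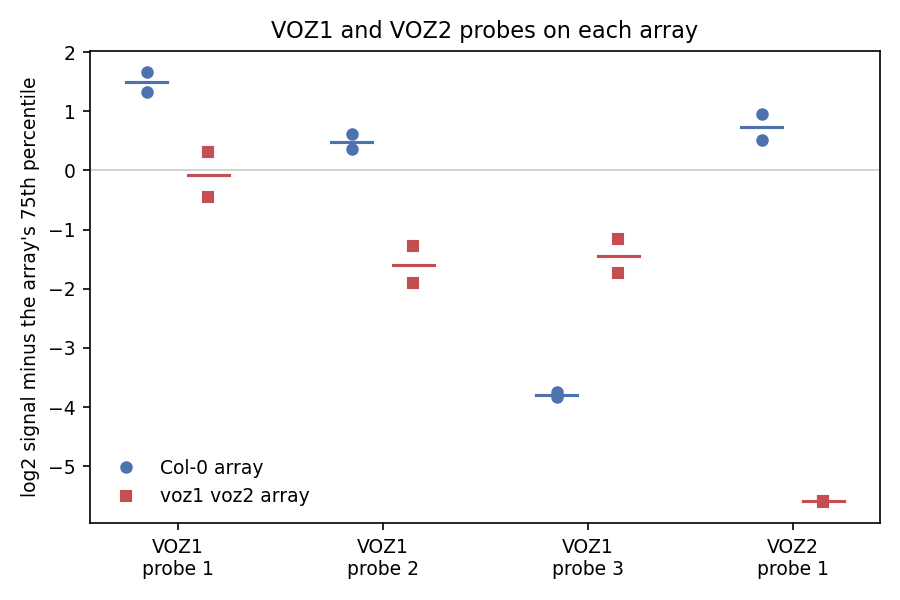
Log2 signal minus the array's 75th percentile (vertical axis) for the VOZ1 probes, numbered by their level in Col-0, and for the VOZ2 probe. Circles are Col-0 arrays, squares voz1 voz2 arrays and lines group means; the third VOZ1 probe is higher in voz1 voz2, and the other probes are lower.

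Of 21385 genes tested, 1002 rose and 1543 fell in voz1 voz2. By the values as measured, also below background, 726 and 1294 of these changed at least 2-fold. The tested probe was not well above background on any voz1 voz2 array for 178 of the genes that fell. The same held in Col-0 for 98 of those that rose. For these genes only a bound holds, which can be under 2-fold, such as at least 1.83-fold for AT2G31690. The 10 largest rises and the 10 largest falls, VOZ2 among the latter, were ranked by the log2 fold change as measured, also below background, so a gene given as a bound need not have changed more than genes outside the 10. SAG12, a cysteine protease gene used as a marker of leaf senescence, rose at least 88.4-fold, from below background in Col-0. SWEET15, also known as SAG29, a sucrose transporter gene, rose 105-fold (log2 fold change 6.72, SE 0.408, limma adjusted p = 0.00317), and AT3G25573, of unknown function, rose 58.1-fold. From below background in Col-0, AT2G23970 rose at least 53.0-fold (79.5 without voz1 voz2 replicate 1 and 35.3 without replicate 2), BGAL7, a beta-galactosidase gene, at least 24.8-fold, AT1G28650, a putative lipase gene, at least 23.5-fold, the carotenoid cleavage gene CCD7 at least 9.05-fold and AT2G05400 at least 8.77-fold. PAP20, an acid phosphatase gene, rose by 4.91 on the log2 scale. AT2G26692, measured above background on 1 of the 2 Col-0 arrays, rose 33.2-fold as measured, a size that is not exact.

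The transcription factor genes AT1G19210, RRTF1, ddf2 and AT5G21960 fell. AT1G19210 fell by 7.48 on the log2 scale (SE 1.35, limma adjusted p = 0.0292), and the log2 fold change was -6.88 for RRTF1 (SE 0.776, 0.00932), -7.40 for ddf2 (0.0180) and -7.34 for AT5G21960 (SE 1.23, 0.0242). LCR85, a gene for a small cysteine-rich protein, fell at least 103-fold to below background, and AT4G37710, a VQ motif gene, at least 18.4-fold. AT2G27270, AT3G01345 and AT3G19550, whose functions are unknown, fell with log2 fold changes of -6.58, -6.28 and -6.14. In voz1 voz2, ddf2, AT5G21960, AT2G27270 and AT3G01345 were above background on 1 of 2 arrays. The log2 fold changes of these genes over all arrays include a signal below background and are not exact. For ddf2, AT5G21960 and AT2G27270 the array below background was voz1 voz2 replicate 2. Without voz1 voz2 replicate 1 their log2 fold changes rest on that signal alone in voz1 voz2 and are not exact either. Leaving out single arrays moved the size of these falls by more than 1.5 times on the linear scale, as follows. Without voz1 voz2 replicate 1 and without replicate 2, the log2 fold changes were -9.60 and -5.36 for AT1G19210, -9.31 and -5.37 for AT5G21960, -8.92 and -5.88 for ddf2, -7.91 and -5.86 for RRTF1, -7.92 and -5.25 for AT2G27270, and -6.73 and -5.55 for AT3G19550. Without Col-0 replicate 1 and without replicate 2 they were -6.51 and -8.29 for ddf2, -6.20 and -7.56 for RRTF1, -5.98 and -7.19 for AT2G27270, and -6.90 and -5.65 for AT3G01345. Without Col-0 replicate 1 the calls of AT1G19210 (adjusted p = 0.0747) and AT5G21960 (0.0579) were lost, and with no filter on dim probes those of AT1G19210 (0.0717), AT5G21960 (0.0624) and ddf2 (0.0511).

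Both mutant arrays lay beyond both Col-0 arrays for 58.4% of all genes, against 33.3% by chance. The counts of called genes rest on limma's pooling of the spread across genes: without it 0 genes passed, with 4052 at an unadjusted p under 0.05. There were 626 higher without Col-0 replicate 1, 479 higher and 921 lower without voz1 voz2 replicate 1, 386 higher and 924 lower without voz1 voz2 replicate 2, and 415 higher and 823 lower with no filter on dim probes.

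Most measured genes of flowering time did not pass the test. In the photoperiod list 1 of 32 measured genes rose, 1 fell and 30 did not pass: COL2, a relative of CONSTANS, rose (log2 fold change 1.26, SE 0.218, limma adjusted p = 0.0265), and CDF1 (AT5G62430), a repressor of CONSTANS transcription, fell by 1.44 (SE 0.199, 0.0154). The log2 fold change was 0.16 for FT (SE 0.30), 0.33 for CO (SE 0.192) and 0.05 for GI (SE 0.254), with adjusted p of 0.783, 0.338 and 0.923. FT lay at -5.77 ± 0.46 in Col-0 and -5.61 ± 0.37 in voz1 voz2 (SD, n = 2). The hour of harvest is not among the sample conditions used here, and levels over the day were not examined. TSF, AP1 and LFY were not well above background on both arrays of either group and were not tested. Adjusted over the list alone, 1 gene rose and 1 fell.

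In the list of the FLC clade and the autonomous and vernalization pathways, 1 of 27 genes rose and 1 fell, and the same counts held adjusted over the list alone. VIN3, which acts in vernalization, fell at least 5.57-fold to below background, and FPA, of the autonomous pathway, rose by 0.84 (SE 0.164, limma adjusted p = 0.0357). FLC had a log2 fold change of -0.06 (SE 0.223, 0.894), SVP of -0.10 (SE 0.187), MAF2 of -0.17, MAF3 of -0.11, MAF4 of 0.26 and MAF5 of 0.49, with adjusted p from 0.144 to 0.894 among these 6 genes. Of 17 measured floral integrator and floral identity genes, 2 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone. SEP3, a floral organ identity gene, rose by 1.34 (SE 0.204, 0.0188), the homeobox gene ATH1 rose by 1.33 (SE 0.169, 0.0121), and SPL5, which promotes the change to flowering, fell by 1.87 (SE 0.169, 0.00574). SOC1 had a log2 fold change of -0.21 (SE 0.164, 0.486) and FUL of -1.25 (SE 0.322, 0.0707); FUL passed without Col-0 replicate 2 (-1.57, 0.0420) and with the mean of its probes (-1.24, 0.0403), its adjusted p ranging from 0.0403 to 0.341 over 13 alternatives without a replicate block.

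The flowering calls near the threshold depended on single arrays. CDF1 (limma adjusted p = 0.0579), ATH1 (0.0539) and SEP3 (0.0710) lost their calls without voz1 voz2 replicate 2, COL2 without Col-0 replicate 1 (0.0694) and without voz1 voz2 replicate 1 (0.0954), and FPA whichever array was left out (0.0566 to 0.195). SPL5 and VIN3 passed without each array. With no filter on dim probes the calls of COL2 (0.0634), SEP3 (0.0503) and FPA (0.0766) were lost, and the 2 FPA probes differed in direction, with a log2 fold change of 0.38 (0.262) for their mean.

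**Figure D2:**
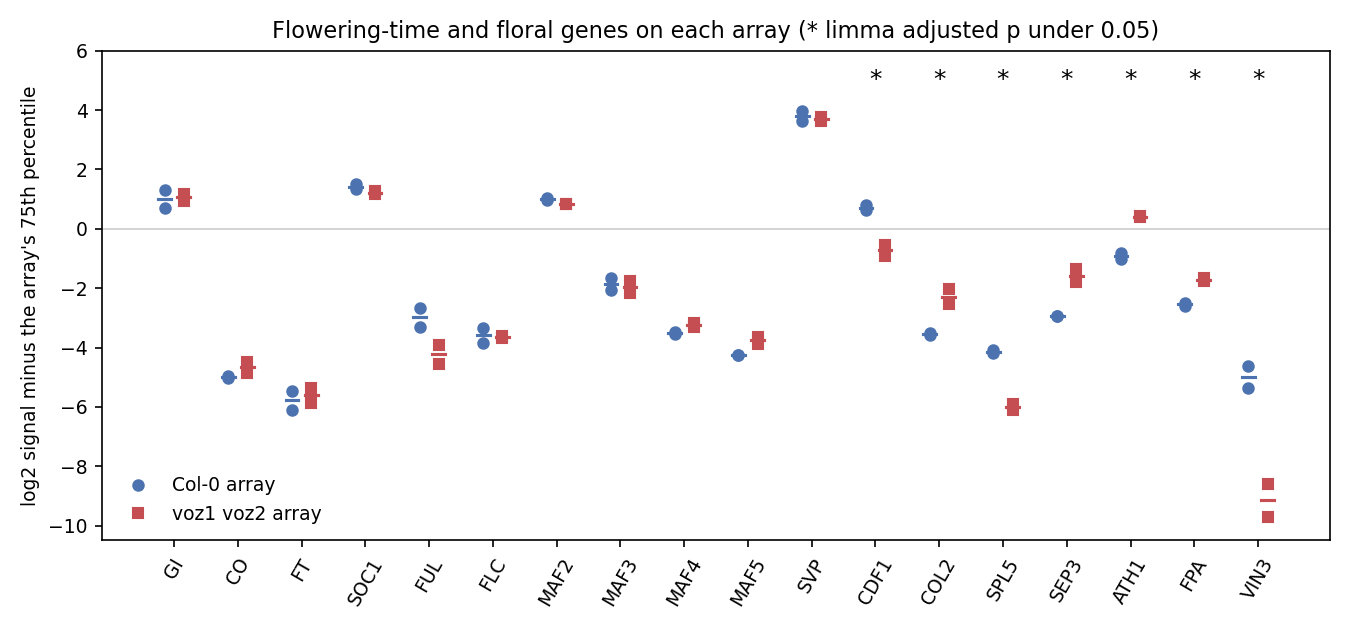
Log2 signal minus the array's 75th percentile (vertical axis) for flowering-time and floral genes, with Col-0 arrays as circles, voz1 voz2 arrays as squares and group means as lines. Stars mark genes past the limma threshold; FT, CO, GI, SOC1, FLC, SVP and the MAF genes carry none, and VIN3 is below background in voz1 voz2.

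Of 24 circadian clock genes 1 rose and 23 did not pass, also when adjusted over the list alone. The gene that rose was RVE2, a MYB-like gene of the REVEILLE family (log2 fold change 1.22, SE 0.205, limma adjusted p = 0.0245), whose call was lost without voz1 voz2 replicate 1 (0.0925) or replicate 2 (0.0810), and with no filter on dim probes (0.0601). CCA1 had a log2 fold change of 0.40, LHY of 0.18 and TOC1 of 0.19, with adjusted p of 0.214, 0.537 and 0.506.

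Genes of defence against pathogens and wounding were lower in voz1 voz2. Of 24 salicylic acid defence genes 19 fell, 0 rose and 5 did not pass, with a median log2 fold change of -1.83; adjusted over the list alone 22 fell. PR1 fell by 2.92 (SE 0.396, limma adjusted p = 0.0146; -3.51 without Col-0 replicate 1 and -2.33 without replicate 2), and PR2 (log2 fold change -3.46, SE 0.324, 0.00619), WRKY38 (-3.05, SE 0.251, 0.00472) and SARD1, a regulator of salicylic acid synthesis (-2.73, SE 0.182, 0.00352), fell too. The list passed camera (adjusted p = 5.8e-16; adjusted p = 0.445 with an estimated correlation). Of 23 jasmonate and ethylene defence genes 16 fell and 0 rose, with a median of -1.55, and 19 fell adjusted over the list alone (camera adjusted p = 8.7e-12; adjusted p = 0.70 with an estimated correlation). JAZ8, a repressor of jasmonate signalling, was 32-fold lower (SE 0.304 on the log2 scale, 0.00317), and VSP2, a jasmonate-induced storage protein gene, fell by 3.59 (SE 0.208, 0.00293).

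Of 12 touch and wounding genes 7 fell and 0 rose, and all 12 fell adjusted over the list alone. MYB15 fell by 4.36 (SE 0.573, limma adjusted p = 0.0131; -5.04 without voz1 voz2 replicate 1 and -3.69 without replicate 2), JAZ1 fell by 2.09 (SE 0.223, 0.00832) and TCH3, a touch-induced calmodulin-like gene, fell by 0.85 (SE 0.166, 0.0351), a call lost whichever array was left out (0.0593 to 0.177). The touch-induced genes TCH2 and TCH4 had log2 fold changes of -1.13 and -1.58 (0.132 and 0.0607). The list's median was -1.29 (camera adjusted p = 1.7e-07; adjusted p = 0.809 with an estimated correlation). Its median difference between replicate 1 and replicate 2 was 0.48 in Col-0 and 0.66 in voz1 voz2; that of the salicylic acid list was 0.18 and 0.02, and that of the jasmonate and ethylene list 0.61 and 0.02.

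**Figure D3:**
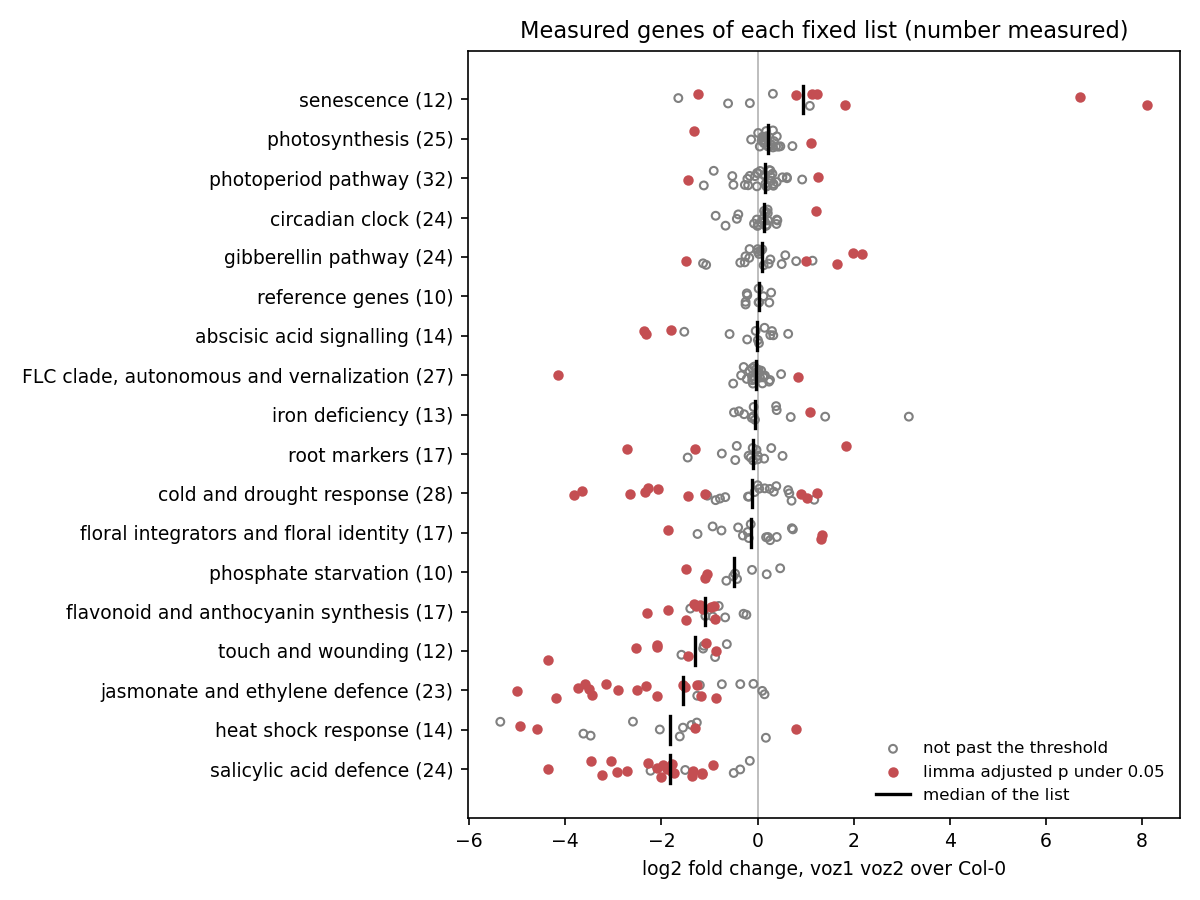
Log2 fold changes of voz1 voz2 over Col-0 (horizontal axis) for the measured members of each list, as measured also where a probe was below background. Filled points passed the limma threshold, open points did not, and vertical bars are list medians; the salicylic acid list has its median at -1.83 and the reference genes at 0.02.

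Of 28 cold and drought genes 3 rose and 8 fell, and 7 rose and 9 fell adjusted over the list alone; the list did not pass camera (adjusted p = 0.283). The cold-response regulators CBF2, CBF1 and CBF3 fell (log2 fold changes -3.83, -3.66 and -2.34, limma adjusted p = 0.0175, 0.0342 and 0.0151), and GOLS2, a galactinol synthase gene, fell by 2.29 (SE 0.18, 0.00447). Without Col-0 replicate 1 the call of CBF1 was lost (0.0876). Without voz1 voz2 replicate 1 and without replicate 2, the values were -4.70 and -2.95 for CBF2 and -4.72 and -2.59 for CBF1. GOLS3 rose by 1.24 (SE 0.177, 0.0165) and COR413IM1 by 0.91 (SE 0.159, 0.0268). GOLS3 lost its call without voz1 voz2 replicate 1 (0.0749) or replicate 2 (0.0523), and COR413IM1 whichever array was left out (0.0575 to 0.150) and with no filter on dim probes (0.0622). Of 14 abscisic acid signalling genes 3 fell and 0 rose, 4 adjusted over the list alone: the phosphatase gene AHG1 fell by 2.37, the abscisic acid synthesis gene NCED3 fell by 1.81 and CYP707A3, of abscisic acid breakdown, fell by 2.32 (list camera adjusted p = 0.283). CYP707A3 lost its call without Col-0 replicate 1 (0.118) or voz1 voz2 replicate 2 (-1.63, 0.0631), and had -3.01 without voz1 voz2 replicate 1. AHG1 was above background on 1 of 2 voz1 voz2 arrays.

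Genes of flavonoid and anthocyanin synthesis were lower in voz1 voz2: 10 of 17 fell and 0 rose, with a median of -1.08, and 14 fell adjusted over the list alone (camera adjusted p = 5.3e-09; adjusted p = 0.445 with an estimated correlation). UF3GT, a glycosyltransferase gene, fell by 1.86 (SE 0.203, limma adjusted p = 0.00869) and GSTF12, which is needed for pigment transport, fell 2.82-fold (SE 0.214 on the log2 scale, 0.0166; 0.0614 without voz1 voz2 replicate 2). Of 10 phosphate starvation genes 3 fell and 0 rose, and 5 fell adjusted over the list alone, with a median of -0.49 (camera adjusted p = 0.00805; adjusted p = 0.531 with an estimated correlation; 0.0681 without voz1 voz2 replicate 1, and 0.00305 to 0.0681 over 13 alternatives without a replicate block). The galactolipid synthase gene MGD3 was 2.15-fold lower, and the noncoding RNA AT4 and IPS1, a related noncoding RNA, fell with log2 fold changes of -1.06 and -1.50. MGD3 lost its call without voz1 voz2 replicate 1 (0.0672) or replicate 2 (0.0833), and AT4 without Col-0 replicate 1 (0.0544), voz1 voz2 replicate 1 (0.106) or replicate 2 (0.0685), and with no filter on dim probes (0.0502). IPS1 lost its call without voz1 voz2 replicate 1 (0.0836) or replicate 2 (0.0705).

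Of 14 heat shock genes 3 fell and 1 rose, and 9 fell and 1 rose adjusted over the list alone, with a median of -1.83 (camera adjusted p = 6.6e-04; adjusted p = 0.827 with an estimated correlation). HSP17.6A (AT1G59860), a small heat shock protein gene, fell by 4.95 (SE 0.766, limma adjusted p = 0.0201; -3.83 without Col-0 replicate 1 and -6.07 without replicate 2), and the heat shock factor gene HSFA7A was 2.46-fold lower (SE 0.198 on the log2 scale, 0.0191), while HSFA3 rose by 0.81 (SE 0.178, 0.0480). HSFA7A lost its call without voz1 voz2 replicate 1 (0.0797) and HSFA3 whichever array was left out (0.0632 to 0.225). With no filter on dim probes HSP17.6A (0.0552), HSFA7A (0.0505) and HSFA3 (0.0958) did not pass, nor did HSFA3 with quantile normalization (0.0549), median scaling (0.0572) or the mean of probes (0.0621). All 14 genes were higher in Col-0 replicate 1 than in Col-0 replicate 2, by a median of 2.1 on the log2 scale, against -0.02 for the same difference in voz1 voz2. The list's median was -1.05 without Col-0 replicate 1 and -3.25 without Col-0 replicate 2.

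Of 12 senescence genes 6 rose, 1 fell and 5 did not pass, and 7 rose and 3 fell adjusted over the list alone, with a median of 0.94. Beside SAG12 and SWEET15, SEN1 (AT4G35770) rose by 1.82 (SE 0.307, limma adjusted p = 0.0247) and ORE1, a regulator of leaf senescence, by 1.25 (SE 0.179, 0.0168). SEN1 lost its call without Col-0 replicate 1 (0.0637) or voz1 voz2 replicate 2 (0.0544), and ORE1 without the latter (0.0763). The gene that fell was SIRK (-1.23, 0.0157; 0.0737 without voz1 voz2 replicate 1), a receptor-like kinase gene also induced in defence. The list passed camera (adjusted p = 0.0437; adjusted p = 0.827 with an estimated correlation), but not without Col-0 replicate 2 (0.0821), with quantile normalization (0.0903) or among genes above background on all 4 arrays (0.169; 0.00356 to 0.169 over 13 alternatives without a replicate block).

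Of 24 gibberellin pathway genes 4 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone (list camera adjusted p = 0.283). GA1, of early gibberellin synthesis, rose by 2.18 (SE 0.233, limma adjusted p = 0.00833; above background on 1 of 2 Col-0 arrays), and the gibberellin-responsive gene GASA6 by 1.99 (SE 0.214, 0.00846; 0.0544 with the mean of its probes, and 0.00238 to 0.217 over 13 alternatives without a replicate block). GA2OX6, of gibberellin inactivation, fell 2.82-fold (SE 0.278 on the log2 scale, 0.0313), a call lost without voz1 voz2 replicate 1 (0.0632) or replicate 2 (0.0998), and with no filter on dim probes (0.0737). Of 25 photosynthesis genes 1 rose, RBCS2B by 1.11 (SE 0.168, 0.0183), and 1 fell, ELIP1 (-1.31, SE 0.203, 0.0201), also adjusted over the list alone. RBCS2B lost its call without Col-0 replicate 1 (0.0528), voz1 voz2 replicate 1 (0.0925) or replicate 2 (0.0682), and ELIP1 without voz1 voz2 replicate 2 (0.0770) and with no filter (0.0525). The photosynthesis list's median was 0.22 (camera adjusted p = 0.0463; adjusted p = 0.853 with an estimated correlation), and the list did not pass without Col-0 replicate 2 (0.258) or voz1 voz2 replicate 1 (0.445), with quantile normalization (0.251), median scaling (0.0976) or a filter on all 4 arrays (0.0547), with a range from 0.00896 to 0.445 over 13 alternatives without a replicate block.

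The remaining lists serve as background. Of 10 reference genes 0 passed in limma, over all genes or adjusted over the list alone, with a median of 0.02 and a largest absolute log2 fold change of 0.284. Of 17 root markers 1 rose and 2 fell, also adjusted over the list alone: the aquaporin gene TIP2;3 rose by 1.84, the nitrate transporter gene NRT2.1 fell by 2.71 (SE 0.219, limma adjusted p = 0.00460) and the root meristem gene PLT2 fell by 1.29 (list median -0.10, camera adjusted p = 0.283). TIP2;3 lost its call without voz1 voz2 replicate 2 (0.0588) and with no filter on dim probes (0.0541), and PLT2 without voz1 voz2 replicate 1 (0.0735). Of 13 iron deficiency genes 1 rose, also adjusted over the list alone: NAS4, of nicotianamine synthesis, by 1.09 (0.0336), a call lost without Col-0 replicate 1 (0.0914), voz1 voz2 replicate 1 (0.148) or replicate 2 (0.0681), and with no filter (0.0755). On the seed storage list 2 genes were measured, EM1 and EM6. The other genes on it, among them CRA1 and SESA1, were not well above background on both arrays of either group. EM1, a late embryogenesis abundant gene, fell by 2.34 (limma adjusted p = 0.0123) and was above background on 1 of 2 voz1 voz2 arrays. Both measured genes fell adjusted over the list alone.

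Among families taken from the array's gene descriptions, 6 of 21 passed camera, and 0 with an estimated correlation. Of 107 genes described as disease resistance proteins 38 fell and 0 rose, with a median of -0.74 (adjusted p = 7.3e-18; adjusted p = 0.126 with an estimated correlation); AT2G26380, above background on 1 of 2 voz1 voz2 arrays, AT5G41750 and AT5G41740 had the smallest p. Of 64 genes with WRKY in their description 16 fell and 2 rose (adjusted p = 4.8e-05), and of 18 receptor-like genes 5 fell (7.3e-04). Of 74 auxin-responsive genes 24 rose and 8 fell, with a median of 0.59 (adjusted p = 5.6e-05), among them SAUR26. Of 42 glutathione S-transferase genes 1 rose and 8 fell (0.0282), and of 24 jacalin genes 2 rose and 5 fell (0.0286). For these last 5 families the result was adjusted p = 0.418 with an estimated correlation. The family described as ethylene-responsive did not pass (3 of 22 rose, 5 fell, adjusted p = 0.365). Nor did the broader family described as heat shock protein, in which 1 of 78 rose and 4 fell (median -0.07, camera adjusted p = 0.112).

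The genes around the disrupted loci were compared with the rest of the genome. Among the 50 measured genes on each side of VOZ1 and of VOZ2 in the order of locus numbers, 22 of 200 (11%) passed the limma threshold, against 2521 of 21183 elsewhere (11.9%). The odds ratio was 0.915, with a 95% interval from 0.558 to 1.43 (Fisher's exact test, p = 0.826). It was above 1 (1.02 to 1.08) under 5 of 8 alternatives, which leave the replicate block and the arrays left out aside, and its upper limit reached 2.004 with no filter on dim probes. Near VOZ1 14 of 100 genes passed, 6 higher and 8 lower, and near VOZ2 8 of 100, 4 higher and 4 lower. On 1 side of VOZ1, AT1G28650 and AT1G28640, the latter at least 7.86-fold higher from below background in Col-0 (12.2 without voz1 voz2 replicate 1 and 5.06 without replicate 2), lie 11 and 10 measured genes away. On the other side GRX480, of the salicylic acid list, 3 measured genes away, fell by 4.35 (SE 0.541, limma adjusted p = 0.0117; -3.57 without Col-0 replicate 1 and -5.14 without replicate 2), and ERF11, 13 away, fell 4.28-fold (SE 0.293 on the log2 scale, 0.0157).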

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

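The tests in this part were chosen after the results were seen, except the test of genes near the VOZ loci, which was planned, and the comparison of the probes of AT1G28640 and AT1G28650, whose outcomes were set before it was run. The bound for the heat shock test was made stricter after its value was seen.

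Probes that could not be assigned to a single gene are outside the gene comparison, and a limma fit of 3562 such probes gave 30 higher and 49 lower in voz1 voz2. The array's own names put MIR826A, at least 17.8-fold higher, MIR169L, at least 10.3-fold higher, and MIR169K, at least 6.58-fold higher, among the rises, all from below background in Col-0. The probe named BT025685 fell by 6.78 (SE 0.330, adjusted p = 0.0313) and was above background on 1 of 2 voz1 voz2 arrays.

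Defence and wounding genes were lower in voz1 voz2. Array scaling cannot be the whole cause, since the largest absolute log2 fold change among reference genes was 0.284 against a median of -1.83 in the salicylic acid list, and a harvest several hours apart is argued against by the clock list, where 1 of 24 genes reached an absolute log2 fold change of 1. Handling of the Col-0 seedlings before harvest cannot be told apart from an effect of the genotype, because TCH2, TCH3 and TCH4 had a median of -1.13 but TCH3 alone passed, and because any difference in handling between the groups would coincide with the genotype. All 14 heat shock genes were higher in Col-0 replicate 1 than in Col-0 replicate 2. Whether that sample accounts for the whole difference in these genes stays open: without Col-0 replicate 1 the median was -1.05, yet the upper quartile was -0.01. An effect of losing VOZ1 and VOZ2 remains an untested candidate explanation.

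AT1G28640 and AT1G28650 rose near VOZ1, while GRX480, closer to it, and ERF11, farther away, fell. A regional difference around both VOZ loci cannot be told apart either: the odds ratio's upper limit was 1.43, but 2.004 with no filter on dim probes, past a bound of 2 that was set after the first value was known. Whether 1 transcript could have been read by both probes also cannot be told apart from a rise of both genes, since the probes share a run of 26 of 60 bases. An effect of the VOZ1 mutation on its close neighbours was not tested, because the positions of the mutations were not used here.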

How the results depend on the processing

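All alternatives here were planned, and the check of the unfiltered fit was chosen after its result was seen. The counts of 1002 higher and 1543 lower genes stayed within 1.5 times under normexp, quantile normalization, median scaling, the authors' deposited values, whose scaling is nearly the main one, the filter on all 4 arrays, the mean of probes, the intensity trend and the fold threshold. With no filter they were 415 and 823 and VOZ1 did not pass (-1.56, adjusted p = 0.0789). Adjusted over the 21385 genes alone, the unfiltered fit still gave 451 and 828 (VOZ1 0.0713), so the added tests explain little of the drop; limma's prior degrees of freedom were 2.42 in place of 3.23. Counting probes gave 552 higher. With no moderation 0 and 0 genes passed, and VOZ1 (-1.56, 0.281) and VOZ2 (-6.32, 0.184) did not, with 2 residual degrees of freedom. With the mean of its probes VOZ1 was at -0.43 (0.253), its probes differing in direction. The groups share the numbers 1 and 2, and the labels do not say that these pair samples. Deviations from the group means correlated at 0.240 for samples with the same number, and the scanner software's fit of spike-in signals had slopes of 0.833 and 0.903 on the replicate 1 arrays and 0 on both replicate 2 arrays, so a batch shared by number stays open. The replicate block gave 1278 higher and 1873 lower genes, 7 lists without senescence (adjusted p = 0.117), 6 families, FUL past the threshold (0.0155), and log2 fold changes of -1.56 for VOZ1 and -6.32 for VOZ2.

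With an estimated correlation 0 lists and 0 families passed in place of 8 and 6, and fry passed 0 lists. In simulation, where genes varied independently, the estimated correlation passed 0 of 20 shifted lists. The odds ratio near the VOZ loci, 0.915 and not past its test, was above 1 under normexp (1.07), quantile normalization (1.08), no filter (1.06), the mean of probes (1.02), the trend (1.05) and the replicate block (1.02), with p from 0.735 to 0.920; the cause was not tested. Named genes not past the threshold changed sign under some alternatives: FLC (0.047 with quantile normalization, 0.010 with median scaling) and GI (-0.18 with the mean of probes). Under normexp, quantile normalization and median scaling, 0 medians of the 14 called lists and families changed sign.

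Leaving out each array in turn, where a lone sample is assumed to vary like the other group, gave 386 to 1008 higher and 921 to 1551 lower genes, 6 to 9 lists, 4 to 8 families, odds ratios from 0.751 to 0.979, VOZ1 from -1.94 to -1.18 (adjusted p 0.0192 to 0.0925) and VOZ2 from -6.54 to -6.10. FT ranged from -0.16 to 0.49, FLC from -0.32 to 0.20, GI from -0.25 to 0.36, MAF3 from -0.33 to 0.10 and SVP from -0.26 to 0.065. Of 58 other named genes past the threshold, 36 passed without each array, 41 passed in each of the other alternatives that tested them apart from no moderation, and 0 changed sign in any alternative that tested them. The filter on all 4 arrays did not test 17 of the 58, 15 of them among the 41. Both mutant arrays lay beyond both Col-0 arrays for all 2545 called genes, so leaving out 1 array could not change a sign. The filters, the trend, no moderation and the replicate block leave a gene's log2 fold change as it is. The unchanged signs are therefore informative only for the other alternatives. Signal over background limits TSF, AP1 and LFY, which have no test, and the genes given as bounds.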

Other observations

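The tests in this part were chosen after the results that prompted them were seen; the lists' other members were written down before their own values were looked at. The bound for the root markers was changed after its value was seen, with no change of reading.

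Genes of developmental cell death, the programmed death of xylem and root cap cells, were higher in voz1 voz2. CEP1, a cysteine protease gene, rose 25.4-fold and prompted the list. Of 7 other members 6 rose in limma, among them DMP4 (log2 fold change 3.30, SE 0.199, adjusted p = 0.00317), PASPA3 (2.57, SE 0.295, 0.00975), BFN1 (2.42, SE 0.238, 0.00692) and MC9 (1.99, SE 0.231, 0.010), while RNS3 had 0.59 (0.0785). The median was 1.99 (camera p = 1.5e-07; p = 0.104 with an estimated correlation). A joint rise of cell death genes is therefore a hypothesis that the 6 risers are consistent with. A larger root share in voz1 voz2 is argued against by the root markers, with a median of -0.10 and an upper quartile of 0.01. Uneven stress or age of the seedlings was not tested for this pattern.

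CCD7 and CCD8 act in strigolactone synthesis, and CCD8 rose 13.2-fold (adjusted p = 0.00389). The hypothesis that strigolactone genes rise together was not borne out: of 9 other measured genes 1 rose, BRC1 by 2.06 (SE 0.195, 0.00635; above background on 1 of 2 Col-0 arrays), with a median of -0.04.

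NRT2.1 fell by 2.71, and the hypothesis that nitrate-induced genes fall together was not borne out either. Of 12 other such genes 0 fell and 5 rose in limma, among them LBD39 by 1.87 (SE 0.155, 0.00480), BT2 by 1.68 (SE 0.175, 0.00796) and the nitrate reductase gene NIA1, 2.15-fold higher (SE 0.169 on the log2 scale, 0.0195). NIA1 lost its call without Col-0 replicate 1 (0.0558), voz1 voz2 replicate 1 (0.0605) or replicate 2 (0.0974). The median was 0.48 (camera p = 0.00122; p = 0.0764 with an estimated correlation).

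Genes with a log2 change of at least 3, as measured also below background, were examined for position. Among those with no probe above background in 1 group, 61 were lost and 37 gained in voz1 voz2. Only bounds hold for their sizes, and some are small. AT2G31690, among the lost, changed at least 1.83-fold, and SK8, among the gained, at least 2.61-fold. Pairs within 5 measured genes of each other numbered 1 among the lost, against a mean of 0.846 in 10000 random draws (one-sided permutation p = 0.575). Among the gained there were 3, against 0.308 (one-sided permutation p = 0.00310): AT1G28640 with AT1G28650, AT2G18180 with AT2G18190, and SK8 with SK7. The draws took genes singly, so adjacent genes of related sequence were not allowed for. A small p in this test therefore does not show that position itself matters. The probes of AT1G28640 and AT1G28650 share a run of 26 bases. Those of AT2G18180 and AT2G18190 share a run of 7, and those of SK8 and SK7 a run of 5. Transcript sequences were not compared, so short runs between probes do not show that each probe reads its own gene alone. Without AT1G28640 there were 2 pairs against 0.288 (one-sided permutation p = 0.0346).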
